A study of Caenorhabditis elegans with 2 samples.

How the data were processed

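Total RNA from whole young adult Caenorhabditis elegans of the N2 strain was measured on 2 one-colour microarrays, 1 for worms fed Escherichia coli OP50, the usual laboratory food, and 1 for worms fed Lysinibacillus sphaericus, a Gram-positive bacterium isolated from soil. Per the labels' protocols, the worms of each group received their bacterium from hatching until young adulthood at 20 °C, and Cy3-labelled cRNA was made from the RNA and hybridised. The groups come from the samples' titles. There is 1 array per diet and no replicate, so no statistical test between the diets was run and no p-value is given. The spread between worm populations is unknown.

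The authors deposited the scanner's intensity values of each spot, on a linear scale, together with flags for background, saturation and outlier spots. Per the file headers, the images were read with Agilent Feature Extraction 11.0.1.1, which subtracted the background and wrote a processed signal and its error for each spot. The headers also show that both arrays lay on 1 slide and were scanned in 1 scan with 1 gain setting, so slide and scan do not separate the diets. Other deposited quantities, such as flags and spot positions, are marks of the software and not levels. The deposited table of the whole series holds the same processed intensity per probe. Its values lay within 0.01 log2 units of the mean processed signal over the spots of a probe for 43596 of 43603 probes on the OP50-fed array and for 43594 on the L. sphaericus-fed array, with array medians of 247 and 369. It is thus on the linear scale, neither scaled between arrays nor centred, and each column follows its own array.

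From the scanner files, control spots were left out, as were 36 spots marked as outliers by the scanner software on either array. No spot was saturated. The log2 of the processed signal was taken, repeated spots of a probe were averaged, and the 75th percentile over all non-control probes was subtracted from each array. Probes numbered 43579, of which 31043 were well above background on both arrays by the scanner's flag and are called measured. A gene's value is the median over its measured probes of the difference L. sphaericus-fed minus OP50-fed. For a gene well above background on 1 array only, on all of its probes, the ratio is a lower bound. It was taken against the higher of the dim probe's own normalized signal and the lowest normalized signal among probes well above background on that array. Where this bound fell on the other side of 0, no fold is given.

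Probes were named through their systematic names, stripped of isoform letters and versions, in a RefSeq gene table of assembly WBcel235. The array design cites an older build, so no coordinates are given. A gene was found for 34290 of the 43579 probes, covering 19800 genes, and 9289 probes stayed without a name here. At the 2-fold level, 15294 genes could be compared. Symbols are the current ones.

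Results are of 3 kinds. The first is the number of genes at least 2-fold higher or lower on the L. sphaericus-fed array. The second describes 56 gene lists fixed from textbook knowledge before the data were examined, 25 of them counted as main results. Each has the number of members at least 2-fold higher, at least 2-fold lower or between, the median relative to the median of all measured genes, and its percentile, which is the percent of 10000 random lists of the same size with a lower median. The random lists were matched on mean normalized signal in 20 bins with random seed 1, and the percentile describes these 2 arrays only. Of the listed names, 16 were not in the gene table and were left out.

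The last kind is the genes named in the text, which follow a rule that was also fixed beforehand. It takes the 15 largest differences in each direction among genes at or above the median signal whose measured probes share a sign, with at most 3 genes of a family. It adds for each list with at least 3 measured members the 2 members furthest up and the 2 furthest down among those at least 2-fold apart, or the 2 brightest where there are none. It also adds the 5 largest lower bounds per direction, and 8 reporter genes in any case (acdh-1, vit-2, fat-7, sod-3, lys-7, T24B8.5, col-19 and daf-16).

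Technical error was taken from probes with repeated spots and from different probes of a gene. The SD over repeated spots was computed on 33 probes with at least 3 spots well above background on both arrays. These errors do not hold the spread between worm populations. The number of arrays limits the precision.

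The alternatives tried were normexp background correction (offset 50), scaling on the median of probes, the 75th percentile over detected probes only, quantile normalization, loess centring along signal brightness (span 0.3), no filter on dim probes, a filter at the median signal, the mean or the brightest probe of a gene, the deposited series table, thresholds of 1.5-fold and 3-fold, genes with at least 2 probes that all pass, and list means. The files used here hold no mean pixel signal, so normexp ran on the median spot and background signals in its place. Leaving the arrays unscaled and scaling on the ribosomal protein genes were added after seeing the data.

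The procedure was tested on simulated arrays with the noise of the repeated spots, an overall gain, and 200 genes shifted by known amounts, for the comparison of the L. sphaericus-fed with the OP50-fed array over 16140 genes. It called 100% of 67 genes shifted by 2 log2 units and 100% of 67 shifted by 1.5. It called 0% of 66 genes shifted by 0.5 and 0% of 15940 unshifted genes. Both simulated arrays were built from the signals of the OP50-fed array, with the same gain for all spots. The real arrays differed by 0.58 log2 units at the median signal and by 1.45 at the 90th percentile, which the simulation left out. The 0% is therefore no rate of false calls for the real comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp.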

Results

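Gene expression was compared between young adult worms raised on E. coli OP50 and young adult worms raised on soil-isolated L. sphaericus, with 1 array for each diet. The study asks how feeding on this bacterium, in place of the control food, alters the worm's transcripts. Of 43803 non-control spots, 33343 (76.1%) were well above background on the OP50-fed array and 33080 (75.5%) on the L. sphaericus-fed array. The L. sphaericus-fed array was brighter, with a median processed signal of 367 against 245 and a 75th percentile of 3348 against 1437. All differences below are L. sphaericus-fed minus OP50-fed on the log2 scale. None has a replicate check, so they describe these 2 RNA samples.

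The arrays differed widely. Of 15294 genes measured on both, 3381 were at least 2-fold higher and 4983 at least 2-fold lower on the L. sphaericus-fed array, together 54.7% of the measured genes. Differences reached 16-fold or more in 87 genes that were higher and 177 that were lower. Of 56 gene lists, the highest medians were those of the vitellogenins, oocyte and eggshell genes, cell cycle genes and germline genes. The lowest were those of the FLP and NLP neuropeptides, male-enriched genes, insulin list, sperm genes outside the major sperm protein family and DAF-16-activated genes. The SD of the difference over genes was 1.61, against 0.15 over repeated spots of a probe and a median of 0.18 between probes in 2761 genes with at least 3 measured probes. Among 2245 genes at least 2-fold apart with 2 or more measured probes, 2197 (97.9%) had all probes on the same side of 0, and 48 had probes on both sides.

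The balance of higher and lower genes depends on how the arrays are scaled. Higher genes made up 40.4% of the 2-fold genes with the 75th percentile, 64.6% with the median of all probes, 50.5% after quantile normalization and 49.7% after loess centring. They made up 81.4% with no scaling and 69.9% with scaling on the ribosomal protein genes. The median difference over all measured genes was −0.20, and these settings moved it by 0.64, 0.29, 0.29, 1.23 and 0.81, in that order. List medians are therefore given relative to the median of all genes, and counts of members use the 75th percentile. Where either count of a list moved by over 1.5 times with median scaling, the counts with that scaling follow, and those with ribosomal scaling where it alone turned or evened the balance or moved a count by over 1.5 times. Each median has its range over all settings behind it. With probes at or above the median signal only, the medians of the cuticle collagens, molting, hedgehog, ER stress, metal stress, vitamin B12, TCA, respiratory chain and epidermis lists turned below all genes. Without the filter on dim probes, those of histones, CUB-like genes, F-box families, fatty acid synthesis, muscle and intestine turned above and that of ABU/PQN genes below. List means turned lysozymes and F-box families above and metal stress and lipase lists below. The brightest probe turned the lipase and respiratory chain lists below, and the mean over probes the respiratory chain.

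**Figure D1:**
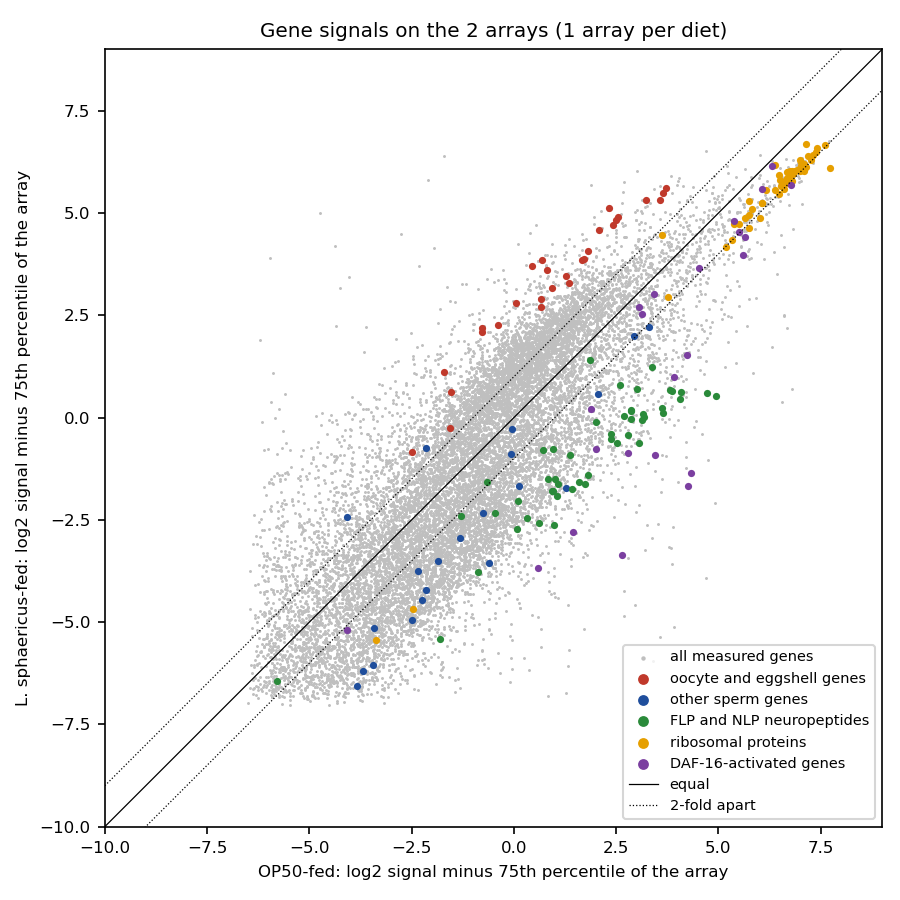
Each point is a gene measured on both arrays, with its log2 signal minus the array's 75th percentile on the OP50-fed array (x axis) and on the L. sphaericus-fed array (y axis), and 5 gene lists in colour. All 28 oocyte and eggshell genes lie above the upper 2-fold line, and 47 of 49 FLP and NLP neuropeptide genes lie below the lower one.

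Among the 15 bright genes furthest on the higher side, 6 belong to classes named here and 9 are given by name only. The lysozyme gene lys-10 was 925-fold higher on the L. sphaericus-fed array, the cuticle collagen gene dpy-14 378-fold, the yolk protein gene vit-1 271-fold and the saposin-like gene spp-17 241-fold, each on a single probe. Bright here refers to the mean log2 signal of both arrays. The signal of lys-10 on the OP50-fed array was 23.1, near the lowest well above background there, 15.7. Its fold thus rests on a value near the floor, as do those of clec-190 (23.3) and srx-86 (22.9) below. The measured probes of lbp-8 and T24B8.5, also given below, had lower normalized signals on the OP50-fed array than that of lys-10. Their folds rest on values near the floor too. On the L. sphaericus-fed array, the signals of gst-34, srlf-14 and acs-23 were near the floor of that array, and so their folds below are uncertain as well. Also given below, med-2 and abu-15 were dim on both arrays. The collagen gene dpy-17 was 150.2-fold higher, with a log2 difference of 7.23 ± 0.09 (SD over 11 probes). The genes F56A4.2, F01D5.3 and C09B8.4 had log2 differences of 9.75, 7.47 and 7.41. Y45F10C.2, C08F11.12, W03F9.4, F22F4.5, C46C2.5, F40G12.11 and the infection response gene irg-8 followed, between 68.5-fold and 24.13-fold higher.

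On the lower side, clx-1 was 523-fold lower, the C-type lectin gene clec-9 485-fold and the lysosomal lipase gene lipl-3, known to be induced by fasting, 393-fold, each on a single probe. The acyl-CoA synthetase gene acs-2, also known to be induced by fasting, was 84.9-fold lower (log2 −6.41 ± 0.26, SD over 6 probes), and the small heat shock gene hsp-12.6 60.9-fold lower (−5.93 ± 0.12, 6 probes). The fungus-induced family gene fipr-24, the lectin genes clec-13 and clec-82 and the cathepsin B-like gene cpr-2 were between 187.5-fold and 122.7-fold lower. W02D7.11, F46C5.1, C23G10.11, Y68A4A.13 and dod-3 were between 175-fold and 60.6-fold lower. The 2 probes of T22F3.11 were far apart (−6.33 ± 2.55).

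**Figure D2:**
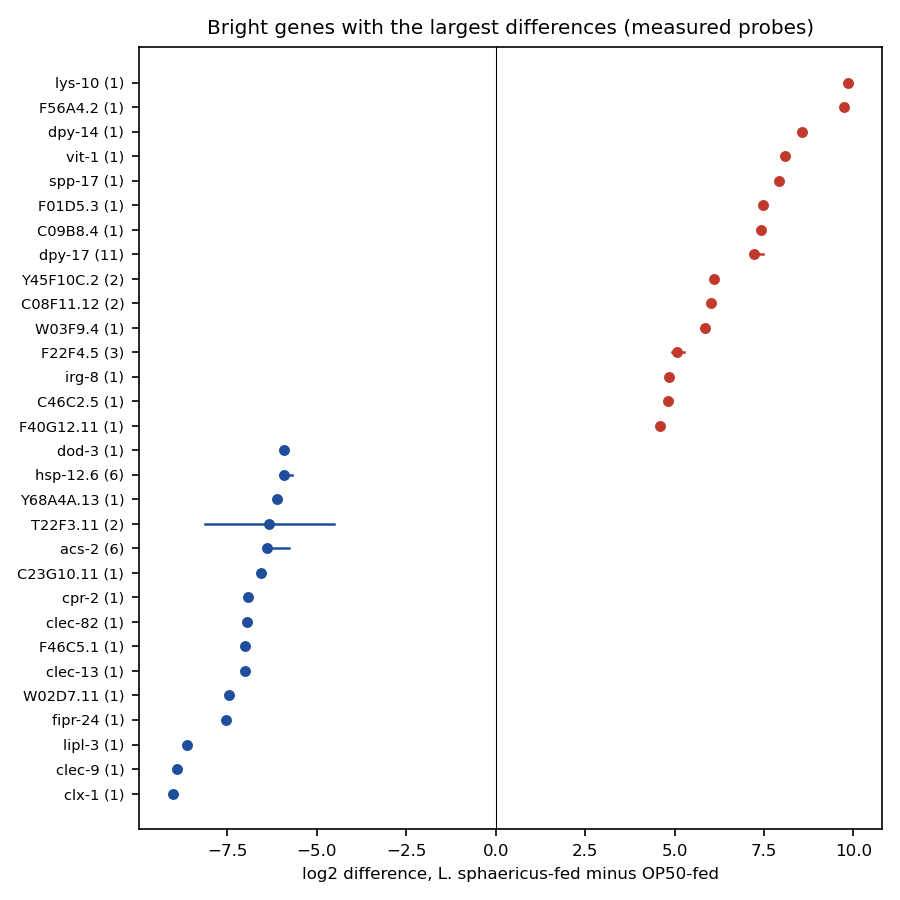
Dots give the log2 difference, L. sphaericus-fed minus OP50-fed (x axis), of the 15 bright genes furthest in each direction (y axis, number of measured probes in brackets), and lines span the lowest to the highest probe. The genes run from 9.85 for lys-10 to −9.03 for clx-1, and the wide line belongs to T22F3.11, whose 2 probes have an SD of 2.55.

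Genes of egg production were higher on the L. sphaericus-fed array. All 28 measured oocyte and eggshell genes were at least 2-fold higher, with a median of 2.45 relative to all genes, above all 10000 random lists (1.90 to 2.73 over the settings, percentile 100%). Among them were oma-2, which acts in oocyte maturation, at 9.56-fold and the eggshell chitin synthase gene chs-1 at 8.92-fold. Of 26 germline and meiosis genes, 22 were at least 2-fold higher and 0 lower (median 1.69, 1.0985 to 1.97 over the settings, percentile 100%), led by the germ granule gene meg-1 (log2 3.23 ± 0.49, SD over 6 probes) and nos-2 (2.71). Of 24 cell cycle and replication genes, 23 were at least 2-fold higher (median 2.06, 1.503 to 2.34 over the settings, percentile 100%), with the cyclin B gene cyb-3 at 2.87 ± 0.10 (3 probes) and the replication helicase gene mcm-7 at 2.65. Of the 5 measured vitellogenin genes, which encode yolk proteins and include near-identical copies, 4 were at least 2-fold higher (median 3.996, 1.89 to 4.28 over the settings, percentile 100%), the median being 1.89 with the brightest probe of a gene. They differed widely, from 271-fold for vit-1 and 16.54-fold for vit-6 to 1.38-fold for vit-2.

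Sperm genes were on the opposite side. Of 21 sperm differentiation genes outside the major sperm protein family, 16 were at least 2-fold lower and 2 higher, with a median of −1.51 relative to all genes (−1.51 to −1.14 over the settings, percentile 0.24%). With ribosomal scaling, 9 of them were lower and 2 higher. The gene spe-4 was 7.98-fold lower, while ssp-19 and spe-39 were 3.12-fold and 2.64-fold higher. Of 27 major sperm protein genes, near-identical copies that a probe may not tell apart, 10 were at least 2-fold lower and 0 higher (median −0.74, −1.30 to −0.46 over the settings, percentile 0.06%), against 0 lower and 1 higher with median scaling. The genes msp-40 and msp-51 were 2.58-fold and 2.22-fold lower, msp-51 turning sign with no scaling. Of 5 measured male-enriched genes, 4 were at least 2-fold lower (median −2.09, −2.096 to −1.40 over the settings, percentile 2.03%), among them cwp-1 and cwp-2 at 4.98-fold and 5.36-fold. Of 8 early zygotic embryo genes, 4 were at least 2-fold higher and 2 lower (median 0.91, 0.50 to 1.59 over the settings, percentile 95.04%), against 4 and 0 with median scaling, with pal-1 and lin-26 4.02-fold and 3.16-fold higher and elt-7 and med-2 2.86-fold and 2.73-fold lower. Of 47 histone genes, which include near-identical copies, 5 were at least 2-fold higher and 13 lower (median −0.27, −0.78 to 0.01 over the settings, percentile 6.73%), a balance of 9 against 5 with median scaling. The genes his-33 and his-47 were 3.44-fold and 2.57-fold higher, and his-11 and his-37 6.36-fold and 4.36-fold lower.

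Genes that DAF-16, the FOXO factor of the insulin pathway, is known to activate were lower on the L. sphaericus-fed array. Of 23 measured, 15 were at least 2-fold lower and 0 higher, with a median of −1.42 relative to all genes, below all random lists (−2.05 to −1.14 over the settings, percentile 0%). They include hsp-12.6 and dod-3 above, and sod-3, a mitochondrial superoxide dismutase gene, at 6.80-fold lower, while lys-7 was at −0.60, a sign that turned with median scaling, no scaling and ribosomal scaling. The gene daf-16 itself was at −0.97 ± 0.35 (5 probes), turning sign with no scaling. Of 40 genes of insulin-like peptides and the insulin pathway, 28 were at least 2-fold lower and 4 higher (median −1.61, −1.68 to −1.26 over the settings, percentile 0%). The insulin-like gene ins-20 was 81.8-fold lower (−6.35 ± 0.45, 9 probes) and ins-11 14.6-fold lower, while ins-34 and ins-12 were higher, with log2 differences of 3.66 and 2.68. Of 19 dauer and TGF-beta genes, 12 were at least 2-fold lower and 2 higher (median −1.26, −1.44 to −0.67 over the settings, percentile 2.03%), against 8 and 4 with median scaling. The steroid hormone gene daf-9 and the TGF-beta ligand gene daf-7 were 7.51-fold and 6.30-fold lower, and lon-1 and daf-36 7.12-fold and 6.89-fold higher.

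In lipid metabolism, the differences went both ways and were large. Among 44 lipase and fatty acid oxidation genes, 8 were at least 2-fold higher and 14 lower (median 0.15, −0.41 to 0.43 over the settings, percentile 39.4%). The balance was 21 against 13 with median scaling, and the median lay below that of all genes after quantile and loess normalization. The genes lipl-3 and acs-2 stood far below the rest, and the acyl-CoA dehydrogenase gene acdh-1 and ech-7 were 8.89-fold and 6.68-fold higher. Of 31 acyl-CoA synthetase and lipid binding protein genes, 16 were at least 2-fold lower and 4 higher (median −1.09, −1.09 to −0.44 over the settings, percentile 0.08%), against 9 and 8 with median scaling and 8 and 9 with ribosomal scaling, with acs-23 8.42-fold lower and lbp-8 and lbp-9 37.9-fold and 3.20-fold higher. Among 22 genes of fatty acid synthesis, desaturation and elongation, 1 was at least 2-fold higher and 9 lower (median −0.07, −0.67 to 0.26 over the settings, percentile 24.5%). This balance was 8 against 4 with median scaling, and the median lay above that of all genes with normexp. The gene elo-2 was 7.72-fold higher, and fat-3 and elo-7 were 7.18-fold and 5.11-fold lower. The stearoyl-CoA desaturase gene fat-7 was well above background on the L. sphaericus-fed array only, at least 521-fold higher.

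Of 24 genes of the TCA cycle, the glyoxylate cycle and gluconeogenesis, 4 were at least 2-fold higher and 2 lower (median 0.10, −0.46 to 0.38 over the settings, percentile 23.3%, below all genes after quantile and loess normalization), against 7 and 1 with median scaling. The glyoxylate cycle gene icl-1 was 16.7-fold lower (−4.06 ± 0.64, 7 probes) and cts-1 2.06-fold lower, turning sign with no scaling, while sucg-1 and sucl-2 were 3.77-fold and 2.88-fold higher. Of 17 glycolysis genes, 7 were at least 2-fold higher and 1 lower (median 1.09, 0.53 to 1.37 over the settings, percentile 98.6%), against 12 and 1 with median scaling, with gpd-1 and hxk-1 4.04-fold and 3.06-fold higher and pfk-1.2 5.84-fold lower. Respiratory chain genes lay near all genes (33 measured, 1 higher, 2 lower, median 0.02, −0.54 to 0.30 over the settings, percentile 47.4%), below all genes after quantile and loess normalization and with 8 higher against 1 lower with median scaling. The gene asb-1 was 3.01-fold higher, cyc-2.2 was 3.37-fold lower, and ucr-2.1 was at −1.04, turning sign with no scaling.

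Neuropeptide genes were lower on the L. sphaericus-fed array. Of 49 FLP and NLP neuropeptide genes, 47 were at least 2-fold lower and 0 higher, with a median of −2.70 relative to all genes (−3.33 to −2.33 over the settings, percentile 0%). The genes nlp-12 and flp-15 were 21.6-fold and 17.5-fold lower. Of 23 neuron markers, 12 were at least 2-fold lower and 1 higher (median −0.83, −1.57 to −0.46 over the settings, percentile 2.44%), against 5 and 1 with median scaling. The lowest were egl-3 and egl-21, whose enzymes process neuropeptide precursors, at 10.1-fold and 8.41-fold, while unc-119 was 2.15-fold higher. Of 207 measured chemoreceptor genes, 110 were at least 2-fold lower and 15 higher (median −0.90, −0.91 to −0.25 over the settings, percentile 0.01%), against 67 and 36 with median scaling, from srh-2 and srlf-14 at 30.8-fold and 19.7-fold lower to srx-86 and srh-211 at 20.9-fold and 3.97-fold higher. Of 208 nuclear hormone receptor genes, 118 were at least 2-fold lower and 3 higher (median −0.91, −1.55 to −0.58 over the settings, percentile 0%), against 52 and 10 with median scaling and 43 and 12 with ribosomal scaling, with nhr-99 and nhr-260 36.9-fold and 14.2-fold lower and nhr-2 and nhr-235 18.7-fold and 4.33-fold higher.

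Immune genes split between their families. Reporter genes of the p38 MAPK PMK-1 pathway were higher, 6 of 11 by at least 2-fold with 1 lower (median 1.42, 0.36 to 2.26 over the settings, percentile 99.7%), against 7 and 0 with median scaling, and the median was 0.36 with probes at or above the median signal only. The reporter T24B8.5, now named sysm-1, was 275-fold higher on 1 measured probe, and its 5 other probes were not well above background on the OP50-fed array. The gene irg-4 was 27.7-fold higher, and catp-3 was 2.48-fold lower. Of 16 infection response genes, 11 were at least 2-fold lower and 2 higher (median −1.30, −1.997 to −1.02 over the settings, percentile 0.51%), against 7 and 2 with median scaling. The flavin monooxygenase gene fmo-2 was 184-fold lower and clec-61 was at −7.03, while irg-4 and irg-5 (11.6-fold) were higher. Of 141 C-type lectin genes, 70 were at least 2-fold lower and 31 higher (median −0.80, −0.96 to −0.14 over the settings, percentile 0.04%), with clec-190 and clec-266 80.9-fold and 79.98-fold higher. Of 14 lysozyme genes, 6 were at least 2-fold lower and 2 higher (median −0.39, −1.47 to 0.22 over the settings, percentile 12.1%), against 5 and 4 with median scaling and 4 and 4 with ribosomal scaling, lys-10 and lys-2 (4.07-fold) being the higher ones and lys-6 and ilys-4 7.75-fold and 5.04-fold lower.

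CUB-like and DOD genes went both ways, with 3 of 12 at least 2-fold higher and 5 lower (median −0.37, −1.44 to 0.32 over the settings, percentile 17.4%), against 5 and 4 with ribosomal scaling, from F55G11.8 and dod-19 at 17.8-fold and 14.5-fold higher to K10D11.2 and F55G11.2 at 38.6-fold and 16.6-fold lower. Saposin-like, ABF and thaumatin-like peptide genes were mostly lower (31 measured, 4 higher, 16 lower, median −0.81, −1.55 to −0.67 over the settings, percentile 0.49%), against 7 and 12 with ribosomal scaling. The genes thn-1 and thn-2 were 32.4-fold and 22.4-fold lower, while spp-23 was 6.23-fold higher. Of 20 epidermal antimicrobial peptide genes, 3 were at least 2-fold higher and 6 lower (median −0.32, −0.52 to −0.07 over the settings, percentile 6.15%), a balance of 5 against 3 with median scaling. Among them cnc-2 (3.39 ± 0.05, 6 probes) and cnc-7 were higher, and cnc-11 (−5.09 ± 0.13, 5 probes) and nlp-32 were lower. FIP and FIPR genes had 17 of 26 members at least 2-fold lower and 6 higher (median −1.23, −2.94 to −0.66 over the settings, percentile 0.06%), against 11 and 7 with median scaling, with fipr-26 38.3-fold lower and fipr-16 and fipr-18 12.62-fold and 6.07-fold higher. The PALS family had 10 of 23 members at least 2-fold lower and 0 higher (median −0.75, −1.14 to −0.36 over the settings, percentile 15.4%), against 9 and 1 with median scaling, led by pals-31 and pals-32 at 15.8-fold and 12.97-fold. The SCL and TTR families had 12 of 67 higher and 25 lower (median −0.36, −0.92 to −0.14 over the settings, percentile 1.88%), a balance of 17 against 16 with median scaling, with ttr-50 and ttr-42 21.7-fold and 21.3-fold higher and scl-17 and scl-2 24.3-fold and 23.97-fold lower. The F-box and MATH/BATH families had 66 of 281 members higher and 94 lower (median −0.07, −0.48 to 0.33 over the settings, percentile 98.6%). That balance was 103 against 61 with median scaling, and the median lay above all genes after quantile and loess normalization. The genes fbxa-200 and fbxc-42 were 18.8-fold and 18.7-fold higher, and fbxa-164 and fbxa-21 41.5-fold and 39.2-fold lower.

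Detoxification families had more lower than higher members, by margins that shrank with median scaling and were gone or turned in some with ribosomal scaling. All measured genes leaned the same way, with 32.6% at least 2-fold lower and 22.1% higher. Only the median of the UDP-glucuronosyltransferases lay below the 2.5th percentile of random lists, and the other lists of this paragraph lay inside. Of 64 UDP-glucuronosyltransferase genes, 34 were at least 2-fold lower and 7 higher (median −0.88, −0.88 to −0.46 over the settings, percentile 0.20%), against 20 and 14 with median scaling, with ugt-34 and ugt-15 35.3-fold and 26.8-fold lower and ugt-62 and ugt-22 at 3.81 and 3.60. Of 46 glutathione S-transferase genes, 21 were at least 2-fold lower and 4 higher (median −0.46, −0.79 to −0.18 over the settings, percentile 4.32%), against 13 and 10 with median scaling and 12 and 13 with ribosomal scaling, with gst-34 and gst-3 257-fold and 16.96-fold lower and gst-38 and gst-26 10.6-fold and 4.11-fold higher. Of 65 cytochrome P450 genes, 26 were at least 2-fold lower and 12 higher (median −0.31, −0.56 to −0.14 over the settings, percentile 38.2%), against 21 and 18 with median scaling and 20 and 20 with ribosomal scaling, among them cyp-37B1 and cyp-35B1 at 24.9-fold and 21.2-fold lower and cyp-13B2 and cyp-14A3 at 9.84-fold and 5.03-fold higher. ABC transporter genes had 22 of 46 lower and 6 higher (median −0.66, −0.79 to −0.42 over the settings, percentile 4.09%), against 12 and 8 with median scaling and 8 and 11 with ribosomal scaling, with wht-5 and wht-9 8.45-fold and 8.39-fold lower and mrp-4 and pgp-8 6.32-fold and 4.47-fold higher. Antioxidant genes had 6 of 21 lower and 0 higher (median −0.40, −0.77 to −0.11 over the settings, percentile 10.3%), against 5 and 1 with median scaling, led by sod-5 at 12.63-fold.

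Of the stress lists, only the heat shock genes had a median below the 2.5th percentile of random lists, and the others lay inside. Heat shock genes had 6 of 14 members at least 2-fold lower and 2 higher (median −0.69, −1.25 to −0.41 over the settings, percentile 1.54%), against 1 lower and 2 higher with median scaling, with hsp-70 and hsp-90 4.99-fold and 3.09-fold lower and hsp-43 and hsf-1 2.23-fold and 2.14-fold higher. The 8 probes of hsp-43 lay on both sides of 0, from −0.63 to 1.35 (SD 0.65). ER stress genes had 3 of 16 higher and 0 lower (median 0.22, −0.34 to 0.50 over the settings, percentile 54.9%), against 6 and 0 with median scaling, dnj-27 and ire-1 leading at 2.60-fold and 2.43-fold. Mitochondrial stress genes had 1 of 11 higher, dnj-10 at 2.45-fold, and 0 lower (median 0.70, 0.43 to 1.03 over the settings, percentile 73.3%), against 6 and 0 with median scaling. Hypoxia and hydrogen sulfide genes had 1 of 13 higher and 3 lower (median −0.50, −0.87 to −0.22 over the settings, percentile 13.8%), against 1 and 1 with median scaling and 2 and 1 with ribosomal scaling, with cysl-3 3.36-fold higher and F22B5.4 and hif-1 4.50-fold and 2.91-fold lower. Metal and osmotic stress genes had 3 of 15 higher and 4 lower (median 0.23, −0.37 to 0.49 over the settings, percentile 44.3%), a balance that was 5 against 4 with median, quantile and loess scaling, the median turning below all genes in the last pair. The metallothionein gene mtl-1 was 51.4-fold lower and smf-3 7.87-fold lower, and cdr-4 and gpdh-1 were 3.10-fold and 2.13-fold higher.

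Of 150 cuticle collagen genes, 30 were at least 2-fold higher and 21 lower (median 0.33, −0.15 to 0.61 over the settings, percentile 90.9%), against 62 and 6 with median scaling and 41 and 13 after both quantile and loess normalization. Beside dpy-14 and dpy-17, the adult-stage collagen gene col-19 was 3.32-fold higher, while col-50 and col-164 were 20.7-fold and 14.2-fold lower. Molting cycle genes had 4 of 24 higher and 2 lower (median 0.33, −0.47 to 0.74 over the settings, percentile 86.9%), against 11 and 0 with median scaling and 9 and 1 after quantile and loess normalization, with mlt-8 and mlt-10 at 1.41 and 1.14, bli-4 at −1.56 ± 1.08 (5 probes) and lrp-1 at −1.16, the last turning sign with no scaling. Hedgehog-related and patched-related genes had 15 of 61 higher and 12 lower (median 0.14, −0.48 to 0.36 over the settings, percentile 87.7%), against 20 and 5 with median scaling, with ptr-2 and grl-22 7.10-fold and 5.68-fold higher and ptr-3 and ptr-22 9.20-fold and 8.86-fold lower. Pharyngeal cuticle ABU/PQN genes had 3 of 12 higher and 4 lower (median 0.22, −0.25 to 0.70 over the settings, percentile 94.4%), a balance of 5 against 2 with median and loess scaling and of 4 against 2 after quantile normalization, with a median below all genes under normexp. The genes abu-12 and abu-14 were 2.47-fold and 2.36-fold higher, and abu-4 and abu-15 6.32-fold and 3.62-fold lower. Epidermis and seam markers lay at the median of all genes (11 measured, 3 higher, 0 lower, median 0.00, −0.69 to 0.38 over the settings, percentile 35.7%), with wrt-2 2.80-fold higher.

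Markers of muscle, intestine and pharynx had medians below that of all genes, muscle and intestine with the turns given above. Muscle markers had 1 of 16 at least 2-fold higher and 2 lower (median −0.26, −0.82 to 0.03 over the settings, percentile 12.5%), against 3 higher and 0 lower with median scaling and 1 and 0 after quantile normalization. The gene dim-1 was at 1.25, and mlc-3 and mlc-2 were at −1.22 and −1.098, both turning sign with no scaling. Intestine markers had 1 of 14 higher and 4 lower (median −0.13, −0.69 to 0.12 over the settings, percentile 12.1%), against 2 and 1 with median scaling and a median above all genes under normexp, with act-5 2.08-fold higher and mtl-2 and ges-1 6.52-fold and 2.85-fold lower. Pharynx markers had 2 of 13 higher and 5 lower (median −0.42, −1.23 to −0.28 over the settings, percentile 18.9%), against 4 and 2 with median scaling, with phat-4 and phat-5 2.36-fold and 2.13-fold higher and phat-3 and myo-2 5.81-fold and 3.34-fold lower. Intestinal peptidase and digestive enzyme genes were lower in 14 of 26 cases and higher in 3 (median −0.86, −1.42 to −0.40 over the settings, percentile 0.03%), against 8 and 8 with median scaling and 8 and 9 with ribosomal scaling. Beside cpr-2, asp-14 was 17.5-fold lower, and pho-1 and pcp-2 were 7.38-fold and 4.94-fold higher. Autophagy and lysosome genes had 6 of 40 higher and 4 lower (median 0.53, 0.02 to 0.81 over the settings, percentile 66.6%), against 20 and 2 with median scaling, with vha-7 and epg-2 4.02-fold and 3.58-fold higher, and hlh-30, a transcription factor of lysosomal genes, and epg-5 3.58-fold and 3.19-fold lower. Ribosomal protein genes lay close together below all genes (64 measured, 0 higher, 8 lower, median −0.67, −1.23 to −0.21 over the settings, percentile 0%), against 1 and 2 with median scaling, with rpl-42 and rpl-24 4.60-fold and 3.98-fold lower.

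Genes that respond to dietary vitamin B12 and amino acids were mixed. Of 16 propionate and vitamin B12 genes, 6 were at least 2-fold higher and 0 lower (median 0.54, −0.02 to 0.92 over the settings, percentile 37.5%). The propionate shunt genes acdh-1 and hach-1, known to be raised when vitamin B12 is scarce, were 8.89-fold and 6.55-fold higher (log2 3.15 ± 0.41 and 2.71 ± 0.38, SD over 3 probes each). Methionine, SAM and one-carbon genes had 4 of 17 higher and 4 lower (median 0.45, 0.17 to 0.72 over the settings, percentile 53.4%), against 8 and 2 with median scaling, with gldc-1 and dhfr-1 2.80-fold and 2.73-fold higher and the S-adenosylmethionine synthetase gene sams-5 and the phosphocholine synthesis gene pmt-1 7.45-fold and 4.70-fold lower.

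**Figure D3:**
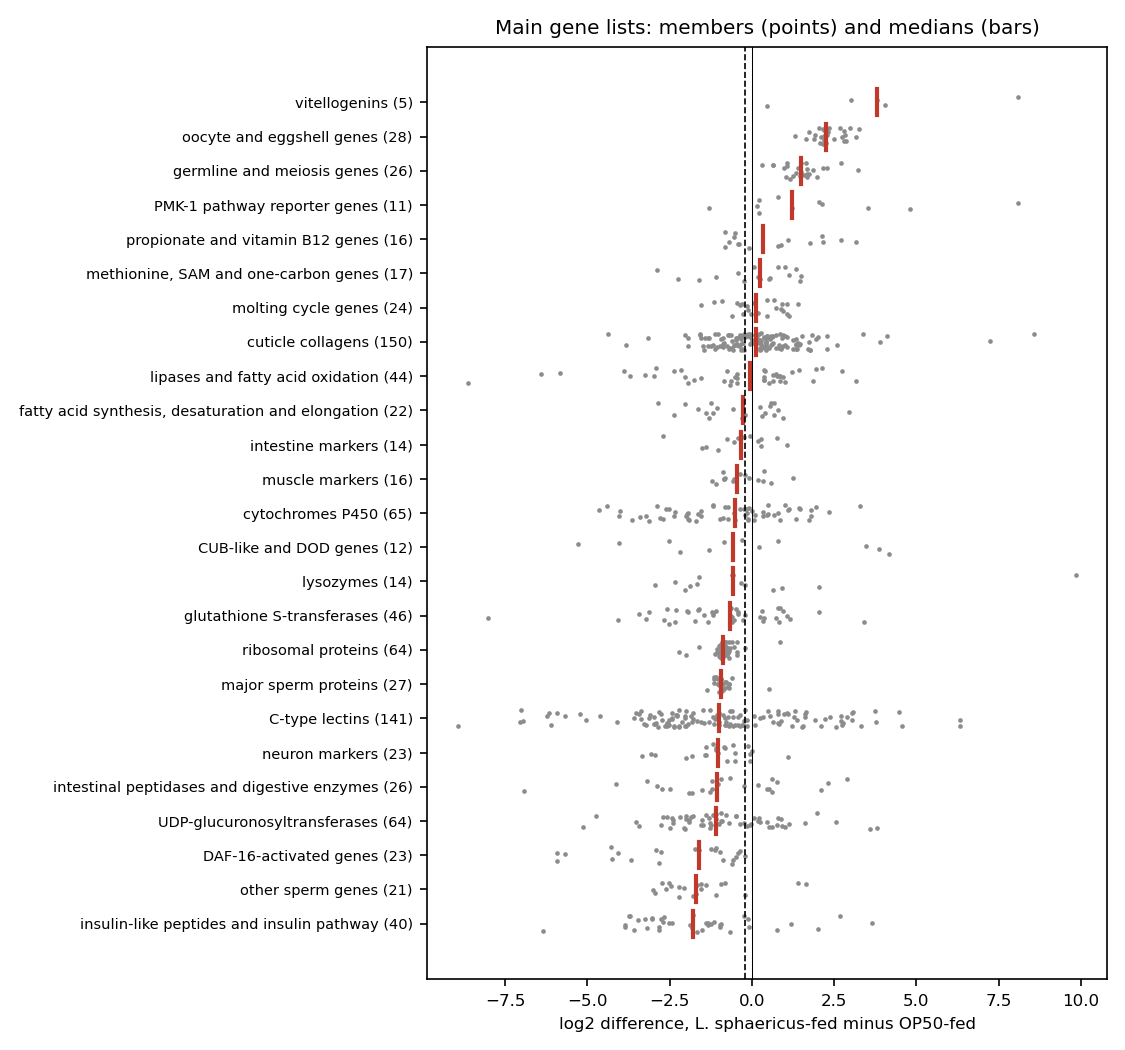
Points give the log2 difference, L. sphaericus-fed minus OP50-fed (x axis), of each measured member of the 25 main gene lists (y axis, number measured in brackets), red bars the list medians, and the dashed line the median of all genes (−0.20). The medians run from 3.80 for the vitellogenins to −1.80 for the insulin list. The dashed line moves with the scaling and so does the side of 0 on which the middle lists lie.

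Some genes were seen on 1 array only. On all of their probes, 729 genes were well above background on the L. sphaericus-fed array alone and 709 on the OP50-fed array alone. The ratio had a lower bound in that direction for 656 and 709 of them. Beside fat-7, the largest lower bounds on the L. sphaericus-fed side were in the collagen gene col-74 at 451-fold, the cuticlin gene cut-3 at 315-fold, acdh-2 at 113-fold (5 probes) and the collagen gene col-121 at 77.8-fold. On the OP50-fed side they were in F10C2.7 at 221-fold, alh-2 at 215-fold, C37A5.6 at 167-fold, F40G12.5 at 143-fold and C37A5.5 at 135-fold.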

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

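Signal in probes outside the gene comparison was looked at because 4325 probes with no matched gene name were measured on both arrays. Of these, 517 were at least 2-fold higher on the L. sphaericus-fed array than on the control array and 1625 were at least 2-fold lower, 11.95% and 37.6% of them, with a median difference of −0.62. They are left out of all gene counts.

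For the patterns below, the tests of spot noise, of dilution, of swapped labels, of the share of the whole germline and of males were chosen only after the results they bear on were seen. The gene lists and rules of the other tests were written first, though some of their genes belong to lists whose medians had been seen. All 8 further fasting-induced genes belong to such lists.

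The spread of the differences was wide, with an SD of 1.61 over genes. Noise of single spots is argued against by the variance between probes of a gene, which was 6.47% of the variance over 15904 probes of genes with at least 2 measured probes. A trend along brightness is argued against as the whole cause, since centring along brightness left 90.7% as many genes at least 2-fold apart. These were not all the same genes: 2857 of the 3381 higher and 3657 of the 4983 lower genes were kept. A different share of germline tissue in the worm populations may account for part of the spread, because both the germline and the oocyte medians lay above all random lists and at least 1.94 log2 units above the muscle and neuron medians, 1.42 to 2.30 over the settings. The diet itself, the stage reached at harvest and the spread between worm populations stay open, as 1 array per diet does not separate them.

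Genes known to be induced by fasting were higher on the OP50-fed array. Dilution of somatic RNA by germline RNA lowers somatic genes alike. As the whole cause it is argued against by the DAF-16-activated genes, at −1.16 relative to muscle markers and −1.29 relative to intestine markers. The argument is less firm with the −0.705 against muscle with the brightest probe of a gene and the −0.97 against intestine after loess centring. It also rests on these reference lists. Relative to all genes, neuron markers at −0.83 and intestinal peptidases at −0.86 lay closer to the DAF-16-activated genes at −1.42. The neuropeptides, at −2.70, lay below them. Food shortage among the OP50-fed worms is a candidate explanation, since 8 further fasting-induced genes (hacd-1, lipl-1, lipl-2, lipl-4, lipl-5, fil-1, fil-2 and icl-1) had a median of −2.93 relative to all genes (−3.63 to −2.63 over the settings) and 7 of them were at least 2-fold lower on the L. sphaericus-fed array. All 8 belong to lists whose medians had been seen, and icl-1 is also among the DAF-16-activated genes. They are thus no independent test. Swapped labels cannot be told apart from food shortage, as 0 genes have a level that the labels fix. A response to L. sphaericus that lowers these genes is open too and was not tested.

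Sperm genes were lower and oocyte genes higher on the L. sphaericus-fed array. A larger share of the whole germline would raise sperm genes as well if its sperm and oocyte parts kept their proportion. In that case it alone leaves their median of −1.51 relative to all genes unexplained, but that value is part of the pattern itself and is no independent test. Males among the OP50-fed worms might raise sperm genes there, but the 5 male-enriched genes lay 0.62 above the neuropeptide genes (0.53 to 1.51 over the settings) and at −1.26 relative to the neuron markers (−1.34 to −0.65), so this cannot be told apart from lower neuronal transcripts. Embryos inside the L. sphaericus-fed adults might raise maternal and early genes, yet 39.1% of 23 measured embryonic patterning genes were at least 2-fold higher, from 17.4% with normexp to 65.2% with no scaling. Over all 15294 measured genes, 22.1% were at least 2-fold higher. Their number moved with the same settings, from 2861 with normexp to 7746 with no scaling. The embryonic median was 0.46 relative to all genes (−0.40 to 0.89 over the settings, percentile 95.2%). These values decide neither way. A later reproductive stage at harvest in the L. sphaericus-fed worms remains an open hypothesis.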

How the results depend on the processing

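Without replicates, the spread of repeated spots (SD 0.15) served as the measure for whether a list median or a named gene's value had moved. No paired analysis was possible because each diet has 1 array and nothing in the labels pairs worms across diets. Leaving the arrays unscaled and scaling on the ribosomal protein genes were chosen after seeing the data. Normexp ran on the median spot signal, since the files used here hold no mean spot signal.

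The counts of higher and lower genes depended on the scaling, the filters and the threshold. They were 3381 and 4983 with the 75th percentile, 5795 and 3177 with median scaling, 2632 and 5686 with the 75th percentile over detected probes, 3977 and 3899 after quantile normalization and 3769 and 3815 after loess centring. With normexp they were 2861 and 5038, with no filter on dim probes 4066 and 6571, and with probes at or above the median signal only 2364 and 1721. Unscaled arrays gave 7746 and 1770, and ribosomal scaling 6367 and 2740. At 1.5-fold they were 4970 and 6415, at 3-fold 1510 and 3320, and for genes with at least 2 probes that all pass 633 and 1128. The mean over probes, the brightest probe and the deposited series table gave 3371 and 4974, 3348 and 4989, and 3381 and 4983. The median of all genes shifted by 0.64 with median scaling, −0.20 with the 75th percentile of detected probes, 0.29 with quantile normalization, 0.29 with loess, 1.23 unscaled and 0.81 with ribosomal scaling.

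Medians of the 25 main lists, relative to all genes, had 325 values under the alternatives, of which 214 moved by less than that SD and 111 by more. The 214 include settings that shift every gene alike, under which such medians cannot move. These are median scaling, scaling on detected probes, no scaling and ribosomal scaling. The deposited series table, also included, holds the same signals. The 214 are therefore no measure of how stable the medians are. No list whose median lay at least 1 from that of all genes changed side. With normexp, the values were −0.51 for major sperm proteins, −1.14 for other sperm genes, 2.73 for oocyte genes, 0.48 for cuticle collagens, −0.22 for lysozymes and −0.19 for CUB-like genes. Further values were −1.27 for DAF-16-activated genes, −0.73 for UDP-glucuronosyltransferases, 0.10 for fatty acid synthesis, 0.72 for vitamin B12 genes, −0.47 for ribosomal proteins and −1.28 for the insulin list. Others were 0.0759 for intestine markers. After quantile normalization, the values were −1.25 for other sperm genes, 2.28 for oocyte genes, 1.28 for germline genes, 0.65 for molting cycle genes, −0.58 for C-type lectins and −0.57 for CUB-like genes. Further values were −0.74 for glutathione S-transferases, −0.14 for cytochromes P450, −0.10 for lipases and oxidation, 0.15 for vitamin B12 genes, −0.21 for ribosomal proteins and −0.40 for intestinal peptidases. Others were −1.46 for the insulin list and −0.32 for intestine markers. After loess centring, the values were 3.82 for vitellogenins, −1.31 for other sperm genes, 2.21 for oocyte genes, 1.0985 for germline genes, 0.18 for cuticle collagens and 0.71 for molting cycle genes. Further values were −0.65 for C-type lectins, −0.64 for CUB-like genes, −0.77 for glutathione S-transferases, −0.72 for UDP-glucuronosyltransferases, −0.13 for lipases and oxidation and 0.06 for vitamin B12 genes. Others were −0.23 for ribosomal proteins, −0.41 for intestinal peptidases, −1.46 for the insulin list and −0.40 for intestine markers. Without the filter on dim probes, the values were 4.28 for vitellogenins, −0.46 for major sperm proteins, −1.27 for other sperm genes, 2.73 for oocyte genes, 1.97 for germline genes and 0.61 for cuticle collagens. Further values were 0.74 for molting cycle genes, −0.14 for C-type lectins, −0.11 for lysozymes, 1.70 for PMK-1 reporters, 0.32 for CUB-like genes and −1.14 for DAF-16-activated genes. Others were −0.18 for glutathione S-transferases, −0.46 for UDP-glucuronosyltransferases, 0.26 for fatty acid synthesis, 0.43 for lipases and oxidation, 0.82 for vitamin B12 genes and 0.68 for one-carbon genes. Further values were −0.39 for ribosomal proteins, −0.58 for intestinal peptidases, −1.26 for the insulin list, 0.0254 for muscle markers, −0.46 for neuron markers and 0.12 for intestine markers. With probes at or above the median signal only, the values were 3.27 for vitellogenins, −1.30 for major sperm proteins, 1.90 for oocyte genes, 1.17 for germline genes, −0.15 for cuticle collagens and −0.47 for molting cycle genes. Further values were −0.96 for C-type lectins, −1.47 for lysozymes, 0.36 for PMK-1 reporters, −1.44 for CUB-like genes, −1.98 for DAF-16-activated genes and −0.79 for glutathione S-transferases. Others were −0.56 for cytochromes P450, −0.67 for fatty acid synthesis, −0.0216 for vitamin B12 genes, 0.17 for one-carbon genes, −1.23 for ribosomal proteins and −1.42 for intestinal peptidases. Further values were −0.82 for muscle markers, −1.57 for neuron markers and −0.69 for intestine markers. With the brightest probe of a gene, the values were 1.89 for vitellogenins, −1.27 for DAF-16-activated genes, −0.28 for lipases and oxidation, 0.72 for one-carbon genes and −0.57 for muscle markers. With the mean over probes, the value was 0.63 for one-carbon genes. With list means in place of medians, the values were 4.16 for vitellogenins, −1.27 for other sperm genes, 2.62 for oocyte genes, 0.49 for cuticle collagens, 0.22 for lysozymes and 2.26 for PMK-1 reporters. Further values were −0.0554 for CUB-like genes, −2.05 for DAF-16-activated genes, −0.68 for glutathione S-transferases, −0.48 for cytochromes P450, −0.58 for UDP-glucuronosyltransferases and −0.41 for lipases and oxidation. Others were 0.92 for vitamin B12 genes, 0.29 for one-carbon genes, −0.68 for intestinal peptidases, −1.44 for the insulin list and −0.0217 for muscle markers.
The cause was not tested for any of these. Over all 56 lists, the balance of members at least 2-fold higher and lower turned in 14 under median, quantile or loess scaling and not in 42. The 42 include balances that median scaling evened, such as the intestinal peptidases at 8 and 8. Ribosomal scaling was not counted there and turned or evened further ones, such as the ABC transporters at 11 higher and 8 lower. The other 31 lists had 401 values, 264 within that SD and 137 beyond it, the 264 again including the settings under which such medians cannot move.

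For the 202 named genes, 1076 of 2358 values lay within that SD, and 1276 beyond it without a change of sign in a gene at least 2-fold apart. Of the genes at least 2-fold apart, 6 changed sign, each with no scaling: msp-51 (0.0724), lrp-1 (0.0711), cts-1 (0.18), ucr-2.1 (0.18), mlc-3 (0.0027) and mlc-2 (0.13). Among those less than 2-fold apart, daf-16 changed sign with no scaling, and lys-7 with median scaling, no scaling and ribosomal scaling. The sign changes with no scaling follow from leaving out the scaling, which shifts every gene by 1.23. Below that gap, the scaling decides the side of 0. Signal over background limits the lists too, since 2128 probes were well above background on the OP50-fed array alone and 1856 on the other alone, and these enter no list median.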

Other observations

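Expression of some gene families was seen on 1 array only in unequal numbers, and no test of these differences was run. Among chemoreceptor genes, 198 were well above background on the OP50-fed array alone and 43 on the L. sphaericus-fed array alone, against 709 and 729 over all genes. The F-box and MATH/BATH families went the other way, with 83 genes on the L. sphaericus-fed array alone and 23 on the OP50-fed array alone. C-type lectin genes had 26 and 17, and cuticle collagen genes 10 and 2, in the same order. Of those seen on the L. sphaericus-fed array alone, 33 chemoreceptor, 78 F-box and MATH/BATH, 25 lectin and 5 collagen genes had a lower bound in that direction, and the rest are not shown to be higher there. Of the early zygotic embryo genes, 6 (pes-1, ceh-51, tbx-37, tbx-38, pes-10 and end-1) were seen on the L. sphaericus-fed array alone and 0 on the OP50-fed array alone. Their lower bounds were small, from 1.102-fold for tbx-38 to 6.79-fold for pes-1. The 6 genes belong to a list fixed beforehand, but the choice to show them here was made after their values were seen.

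Genes whose sequence names share a clone, and which therefore lie close together, were counted per clone, chosen here after the values were seen. Of 2029 clones with at least 4 genes measured or bounded, 17 had at least 75% of their genes 4-fold or more lower on the L. sphaericus-fed array and 3 had as many 4-fold or more higher. With genes shuffled over these clones 1000 times, a comparison also chosen after the values were seen, the mean numbers were 5.82 and 0.476 and the highest 13 and 4, and 0 and 9 shuffles gave as many. All 6 genes of clone T26H5 were at least 4-fold lower, with a median of −4.23, as were 7 of 8 in C17B7 (median −3.69) and 8 of 9 in F09C6 (median −3.08). The remaining gene of C17B7, fbxa-65, was at 0.16, and that of F09C6, F09C6.10, was at least 21.1-fold higher on the L. sphaericus-fed array. On the higher side, 4 of 5 genes in R04D3 were at least 4-fold higher (median 3.56), and the other, srd-39, was at least 3.15-fold lower. No explanation was tested for these clones.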
